A study of Mus musculus with 6 samples.

How the data were processed

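The series held 6 samples: 3 gene-expression libraries of GFP-positive lung cells and 3 hashtag libraries, both numbered as replicates 1 to 3 per the labels. The libraries were made with 10x 3' chemistry and sequenced on an Illumina NovaSeq per the labels, and the labels describe the collected cells as epithelial or other cells. Per the submitters' processing notes, Cell Ranger 5.0.0, Scanpy 1.6.0 and Seurat 3.0.2 were used with GRCm38, with no role or order given. The deposited table held raw UMI counts of 33198 genes in 17915 cells, 142721696 UMIs in all, and every value was a whole number of 0 or more. The cell names began in 3 ways, which were taken as 3 libraries and called A, B and C. No label links these to the replicate numbers, and no annotation of age, hairpin, animal or hashtag was in the table. The planned contrasts of age and hairpin were therefore not run, and cells were never split by their Nupr1 level. The hashtag libraries were not analysed here.

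The deposited cells had been filtered before deposit: the highest mitochondrial share was 4.99, 5.00 and 4.99% and the highest number of genes 5921, 5998 and 5901 in libraries A, B and C. Libraries A, B and C held 33614776, 49448688 and 59658232 UMIs. Library B had no cell under 10164 UMIs, while the lowest cells of A and C had 502 and 506. Cells with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept (17771; 71, 0 and 73 removed). Doublets were scored by the share of simulated doublets among a cell's neighbours (2 simulated per cell), and the highest scores were removed at 0.8% per 1000 cells of the library (273, 80 and 614 cells). This left 5566, 3091 and 8147 cells, 16804 in all.

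Counts were scaled per cell and log transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered with the Leiden method at resolution 1 over 15 neighbours (seed 1), which gave 26 clusters. Nupr1, the reporter genes and the genes of the 12 fixed lists were left out of the clustering. Clusters were named by 18 lists of marker genes, of which the cycling list was left out of the naming score. The score was the mean of marker CPM, each relative to its highest level over clusters. It used markers of at least 50 CPM in some cluster and at least 3 such markers per class. Leading genes were ranked by the fold against all other cells, with a prior of 10 CPM. A cluster stayed unnamed with under 20 cells, or where markers of another class outnumbered its own among its 10 leading genes. It also stayed so where the second class reached 0.75 of the first one's score and fewer than 4 own markers were among them. The same held with under 3 markers detected, or for shallow cells with no own marker among the leading genes. Names end in "like" because they rest on these markers alone. AT2-like cells were clusters 2, 3, 4 and 6, and macrophage-like cells were clusters 0, 1, 5, 7, 9, 11, 12 and 13.

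UMIs were summed per library and class. Classes with at least 50 cells in every library (AT2-like, macrophage-like and cluster 8, 9 sums) were fitted together with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F test, library as a block), and AT2-like clusters 2, 3 and 4 in a second fit of 9 sums, each against the mean of the other 2. Common dispersions were 0.0121 and 0.00251. P-values were adjusted by the Benjamini-Hochberg method over all genes of a fit (16827 and 12285), with a threshold of 0.05. The SE is the log2 fold change divided by the square root of F. The block was kept because sums of a library deviated together (correlation of deviations across genes from 0.375 to 0.789 for pairs of classes of a library). The library, not the cell, is the replicate (n = 3), and nothing states which animals make up a library.

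Levels are CPM scaled by TMM factors over all classes with at least 10 cells in each library, or over the 9 cluster sums for comparisons of AT2-like clusters. For a gene with 0 UMIs in a group the fold is a lower bound against a floor of 3 UMIs over the group, and with 1 to 3 UMIs it is the ratio of the scaled sums with an exact binomial 95% interval, which holds counting error only. Shares of cells with a Nupr1 UMI were taken after thinning cells to 2000 UMIs. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, beside an estimated correlation. The gene lists, marker lists, the kinds of test (edgeR and camera) and 26 alternatives were fixed before the data were examined. So was the rule for named genes: Nupr1, reporters, the 10 largest rises and falls with the same sign in every library (mitochondrial, ribosomal and model genes, markers and clustering genes left out), and up to 4 members of a list that passed and 2 that did not. Further list members and cell type markers given beside them, such as Krt8, Isg15 and Scgb1a1, were chosen after their values were seen.

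The contrasts of cluster 8 and of AT2-like clusters 2, 3 and 4, with cluster 6 left out, were set only once the clusters were known. Also chosen after the data were seen were the naming score, whose first form misnamed macrophages, the rule that left cluster 8 unnamed and the removal of list genes from the clustering. So were the rank-based doublet calls (the automatic threshold of Scrublet marked almost no cell), the classes of at least 10 cells, the fits of matched groups, and the fits without cluster 6 and the airway-like cells of cluster 8 (over 100 Scgb1a1 UMIs per 10000; 15 cells). Positions are those of GRCm38 in GENCODE release M21, which held 32836 of the 33198 genes by name. In simulated counts with the same depth and dispersion, a 2-fold change was recovered for 85.1% of genes between AT2-like and macrophage-like cells, 59.7% between cluster 8 and AT2-like cells and 91.0% between AT2-like clusters, with 6, 5 and 3 unchanged genes called. At 1.5-fold the shares were 61.2, 38.8 and 62.7%, and at 4-fold 97.0, 89.4 and 100%. The rates between AT2-like clusters are for cluster 3 against cluster 4. The reported calls set each cluster against the mean of the other 2, which was not simulated. The changed genes were drawn only from those above a minimum expected count. All other genes had the same profile in every class, and the library effect was set by hand. The rates therefore say nothing of rare genes or of classes that differ in most genes. Other tools were R 4.3.3, DESeq2 1.42.0, Python 3.11.15, Scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.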

Results

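Lung cells sorted for GFP were profiled 4 weeks after hyperoxic injury, in mice over 2 years old and mice 12 to 16 weeks old that had received a control hairpin or hairpins against Nupr1. The table held 17915 cells in 3 gene-expression libraries, called A, B and C (5910, 3171 and 8834 cells; median 5335, 14747 and 6413 UMIs per cell). No cell carried an age, a hairpin or an animal, so no contrast of age or of Nupr1 hairpins could be drawn, and whether the hairpins lowered Nupr1 could not be measured. Nupr1, the reporters and 12 fixed gene lists were instead compared between cell classes within the libraries. The 3 hashtag libraries were not analysed here.

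Nupr1 (chromosome 7, 126623249 to 126630861, minus strand) was highest in cluster 8, AT2-like and fibroblast-like cells in these libraries. Some animals had received hairpins against Nupr1 itself, and the share of their cells in each class is unknown. Differences in Nupr1 between classes or clusters can therefore not be told apart from differences in hairpin or age make-up. Hairpin and age make-up may also add to the differences in other genes and lists given below. In AT2-like cells Nupr1 stood at 396, 379 and 326 TMM-scaled CPM in libraries A, B and C (mean ± SD 367 ± 36.6, n = 3 libraries), against 31.3, 39.4 and 30.2 in macrophage-like cells (33.6 ± 5.03). An unnamed epithelial group, cluster 8, had 588, 522 and 395 (502 ± 97.8). Fibroblast-like cells reached 343 ± 60.0 and cluster 15, a second unnamed epithelial group, 181 ± 29.4. AT1-like cells had 45.4 ± 31.3 from 42 UMIs in all, monocyte or dendritic cells 39.6 ± 36.9 (18.6 without library C, 6.91 with a stricter cell filter), endothelial-like cells 27.7 ± 15.1 and B-cell-like cells 7.46 ± 8.86 from 5 UMIs (2.56 without library A, 13.3 with the stricter filter and 14.9 with called doublets kept).

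With each cell thinned to 2000 UMIs, 40.7 ± 2.27% of AT2-like cells and 42.9 ± 3.94% of cluster 8 carried a Nupr1 UMI (mean ± SD of 3 libraries, GFP-sorted cells). The share was 6.14 ± 1.56% in macrophage-like cells and 1.85 ± 1.85% in B-cell-like cells (0.926% without library A), the class taken as background for Nupr1. Fibroblast-like cells gave 39.4 ± 8.08% and cluster 15 gave 26.8 ± 3.07%. Cells with fewer UMIs than that were left out of the shares (6, 0 and 1 AT2-like cells, 26, 0 and 36 macrophage-like cells and 15, 0 and 37 B-cell-like cells in libraries A, B and C).

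The GFP reporter was highest in the epithelial classes by mean, though in library A fibroblast-like cells (1257 CPM) exceeded AT1-like cells (1026). It stood at 2283 ± 234 CPM in cluster 8, 2179 ± 163 in cluster 15, 2012 ± 313 in AT2-like cells and 1541 ± 537 in AT1-like cells, then 1211 ± 390 in fibroblast-like and 713 ± 38.2 in macrophage-like cells. Endothelial-like (205 ± 90.8), monocyte or dendritic (159 ± 37.4) and B-cell-like cells (157 ± 32.8) were lowest. The tdtomato reporter followed the library: AT2-like cells had 600 CPM in library B against 107 in A and 89.3 in C, and macrophage-like cells 293 against 52.1 and 54.1. Cre transcripts were few, at 1.86 ± 0.0904 CPM in macrophage-like cells (125 UMIs) and 0.541 ± 0.288 in AT2-like cells (23 UMIs).

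**Figure D1:**
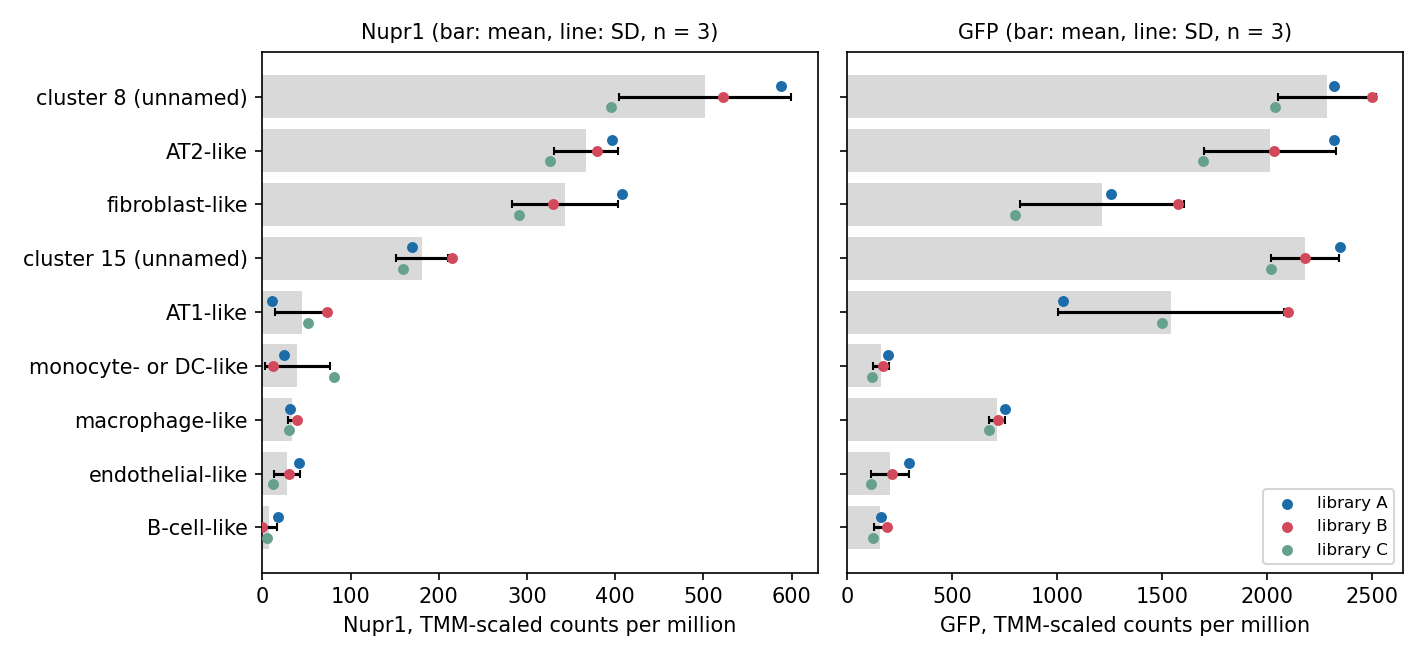
Nupr1 and GFP in TMM-scaled CPM (x axes) for each cell class (y axis). Bars are means and error bars SDs of 3 libraries, and points are single libraries. Nupr1 is highest in cluster 8 (mean 502), AT2-like (367) and fibroblast-like cells (343), while GFP also reaches 713 in macrophage-like cells.

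Macrophage-like cells were the most frequent class in each library with the reported processing. They made up 47.3, 47.3 and 60.0% of the analysed cells of libraries A, B and C (51.5 ± 7.38%, 8984 cells), ahead of AT2-like cells at 40.3, 42.5 and 25% (35.9 ± 9.55%, 5593 cells). Cluster 8 (489 cells, 3.12 ± 1.24%) led with Ccl20, Scgb1a1, Pglyrp1 and Ly6i and was left unnamed, since club and transitional alveolar markers both scored high in it. At resolution 2 a group of 479 cells, 432 of them from cluster 8, took the name club. With more variable genes, the group that shared the most cells with cluster 8 (559 cells) stayed unnamed. A separate group of 20 cells took the name club there. Cluster 15 (177 cells, 1.32 ± 1.02%, and 0.730% without library B) led with Sh3rf3, Ano1, Ndnf and Areg, scored highest for AT2 markers and had the AT1 gene Ager among its leading genes. Endothelial-like (2.31 ± 2.01%, and 1.21% without library C), monocyte or dendritic (1.63 ± 0.722%), fibroblast-like (1.47 ± 0.547%, 0.653% with doublets kept, and no such class with the stricter filter), B-cell-like (0.753 ± 0.364%), T or NK (0.725 ± 0.451%), AT1-like (0.655 ± 0.211%) and neutrophil-like cells (0.461 ± 0.620%, with 0 cells in library B, and 0.108% without library C) followed. A stricter cell filter gave means of 36.6% macrophage-like and 36.1% AT2-like cells, with fewer macrophage-like than AT2-like cells in library A (38.8 against 40.3%) and B (31.0 against 42.7%). Keeping called doublets gave 40.1 and 34.3%, with the same order in A (37.8 against 38.3%) and B (34.5 against 41.8%). Clusters with 10.6 and 10.5% of the cells had no name in these 2 settings. AT2-like cells were also ahead with list genes kept in the clustering in A (40.7 against 39.4%) and B (44.8 against 36.4%), and at resolution 2 in B (44.9 against 34.6%). Library B held no cell under 10000 UMIs, against 94.5% of the cells of library A and 88.4% of library C, so its shares are shares of deep cells. These are shares of sorted cells and not of the lung.

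**Figure D2:**
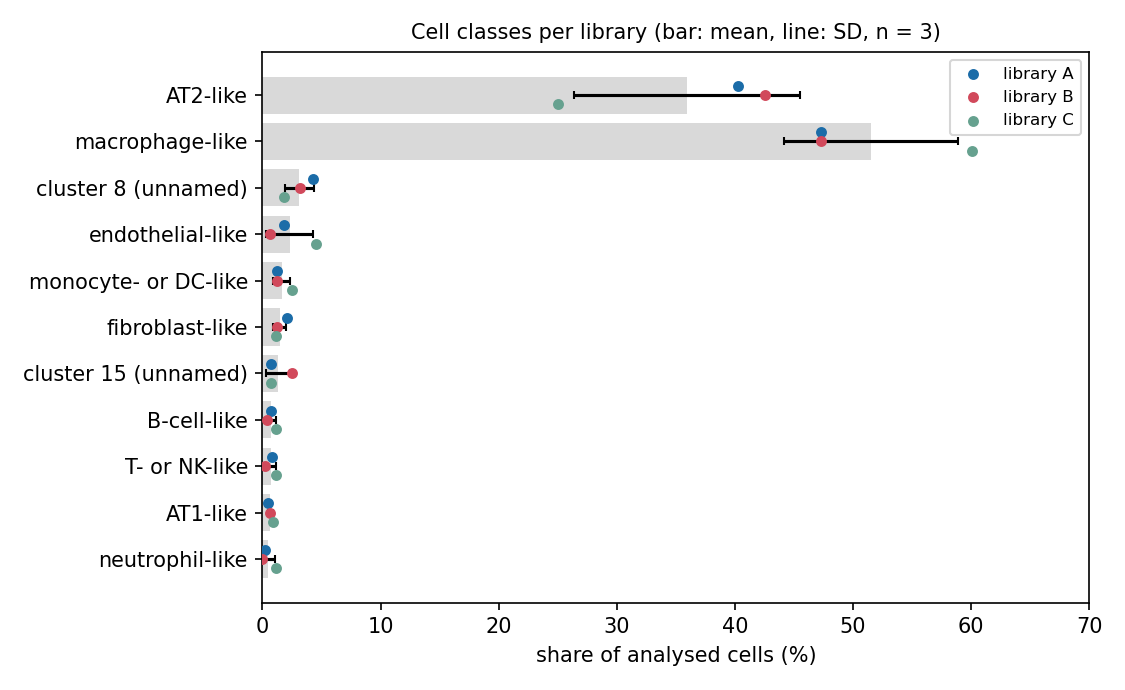
Share of analysed cells (percent, one axis) in each cell class (the other axis); bars are means and error bars SDs of 3 libraries, points are single libraries. Macrophage-like cells lie between 47.3 and 60.0% and AT2-like cells between 25 and 42.5%.

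Between AT2-like and macrophage-like cells, the surfactant lipid, AT2 stem and dissociation lists were higher in the first and the proliferation, interferon and senescence lists in the second by camera with a preset correlation. None of these passed with an estimated correlation (adjusted p from 0.124 to 0.526). Nupr1 was higher in AT2-like cells (log2 fold change 3.24 ± 0.12 SE, adjusted p = 6.36e-11), and so was Lcn2 (6.37 ± 0.27, adjusted p = 2.04e-10; 1379 ± 91.5 against 14.7 ± 6.91 CPM), each in 3 of 3 libraries. Scd1 (5.91 ± 0.22; 6625 ± 623 against 95.3 ± 24.4 CPM), Lpcat1 (6.06) and Fasn (5.55) were higher in AT2-like cells, while the elongase gene Elovl6 was lower (-6.81 ± 0.17; 0.734 against 72.8 CPM, with 46.8 ± 26.3 in fibroblast-like cells). Of 16827 genes tested over the sums per library and class, 6268 were higher and 7107 lower in AT2-like cells (edgeR quasi-likelihood test, adjusted p under 0.05, library as a block). The classes were formed from the same cells' expression, so these p-values measure only how far a difference repeated over the 3 libraries.

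Outside the lists and the genes used for clustering, the largest rises in AT2-like over macrophage-like cells included Olfr171, Iyd and Mbl1. Olfr171 had 8.53 ± 0.30 (29.4 ± 1.90 CPM in AT2-like cells) and Iyd 8.30 ± 0.38 (37.0 ± 16.1). The ranking used this contrast alone and does not show that a gene is particular to AT2-like cells. Mbl1 (chromosome 14, 41151458 to 41159601, plus strand) had 1179 UMIs in AT2-like against 2 in macrophage-like cells, a 929-fold ratio of the scaled sums (95% counting interval 257 to 7681). Aif1l was at least 165-fold and Sytl5 at least 138-fold higher in AT2-like cells, with 0 UMIs in macrophage-like cells set to a floor of 3 over the group. In the other direction Nlrp1b (chromosome 11, 71153102 to 71230733, minus strand) had 2 UMIs in AT2-like and 2069 in macrophage-like cells, a 656-fold ratio (181 to 5423), and reached 30.6 ± 4.30 CPM in macrophage-like cells. With 0 UMIs in AT2-like cells, Kcna3 was at least 64.3-fold, Ccdc180 at least 57.3-fold, Ucp1 at least 49.1-fold and E2f8 at least 42.9-fold lower there.

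GFP was higher in AT2-like cells (1.28 ± 0.09, adjusted p = 3.49e-08) and Cre lower (-2.01 ± 0.43, adjusted p = 8.07e-04), each in 3 of 3 libraries. Surfactant lipid synthesis had 14 of 16 genes higher and 1 lower, with Ldlr level (-0.06, adjusted p = 0.620). The AT2 stem and Wnt list had 7 of 8 higher, led by Nkx2-1 (6.32), Etv5 (6.01) and Axin2 (5.90), while Id2 did not differ detectably (0.00, adjusted p = 0.973). Of 12 proliferation genes 11 were lower, such as Mki67 (-5.81; 0.877 against 44.6 CPM) and Top2a (-5.47), with Tyms level (-0.19, adjusted p = 0.293). Cluster 11 of the macrophage-like cells (301 of 8984), led by Top2a and Mki67, had a cycling score of 4.66, against -0.857 to 0.378 in the other macrophage-like clusters. The senescence and p53 list had 2 of 12 higher and 10 lower, among them Cdkn2a (-6.59), Serpine1 (-5.00) and Gdf15 (-2.78). Interferon genes were mostly lower (2 of 17 higher, 11 lower; Ifit2 -5.19, Gbp2 -4.52, but Usp18 2.78). Dissociation genes were mostly higher (8 of 12 higher, 2 lower; Jun 3.50, Egr1 3.18, Dusp1 -1.23).

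The transitional alveolar list had 10 of 15 genes higher in AT2-like cells (Krt8 6.30, Krt18 6.08, Clu 6.08) and 5 lower (Plaur -5.73). Iron genes went both ways, with 9 of 26 higher (Slc39a8 5.61, Tfrc 3.80) and 17 lower (Ncoa4 -4.60, at 16.5 against 349 CPM; Slc40a1 -3.63). So did the integrated stress response (9 of 20 higher, 8 lower; Vldlr 6.31, Ddit4 4.81, Phgdh -4.99, Slc7a11 -4.47, Ddit3 0.15 with adjusted p = 0.344). The ferroptosis and glutathione list had 5 of 15 higher and 9 lower (Gclc 3.75, Alox5 -6.39, Nqo1 -0.58 with adjusted p = 0.104). NF-kB genes were split as well (6 of 14 higher, 5 lower; Il33 6.56, Cxcl5 with 122 against 2 UMIs and a ratio of 96.1, counting interval 26.1 to 803, Cxcl2 -4.24, Il6 -0.10 with adjusted p = 0.452). MHC class II was split, with Cd74 at 0.58, H2-DMa at -1.12 and H2-Ab1 at 0.07 (2 of 7 higher, 2 lower). Adjusted over the list alone, these 12 counts came out the same. By camera with a preset correlation, surfactant lipid synthesis, the AT2 stem and Wnt list and proliferation (each adjusted p = 0.00139), senescence (adjusted p = 0.0153), interferon and dissociation (both adjusted p = 0.0476) passed. None of the 6 did with an estimated correlation (adjusted p = 0.124 for the stem and proliferation lists, 0.526 for the others). For the integrated stress response and MHC class II the median (-0.12 and 0.07) and the mean (0.15 and -0.12) differed in sign.

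Against AT2-like cells, cluster 8 had the interferon and MHC class II lists higher and the surfactant lipid list lower by camera with a preset correlation. None of these passed with an estimated correlation (adjusted p from 0.111 to 0.270). Ccl20 (chromosome 1, 83116766 to 83119167, plus strand) was the gene with the largest fitted rise (9.75 ± 0.16, adjusted p = 5.48e-12; 1373 ± 277 against 1.59 ± 0.398 CPM). Gbp2 (6.13 ± 0.19; 377 ± 78.7 against 5.38 CPM), Ifit2 (6.67) and Gbp3 (5.59) rose with it, as did Cldn4 (5.29 ± 0.41; 102 against 2.92 CPM). Scd1 fell by 1.63 on the log2 scale (± 0.19; 2132 ± 411 against 6625 ± 623 CPM). Nupr1 was modestly higher (0.44 ± 0.11, adjusted p = 0.0119, in 3 of 3 libraries). This call was lost without library C (0.52, adjusted p = 0.0520), without the library block (0.45, adjusted p = 0.0920) and without the filter on low counts (0.25, adjusted p = 0.0777). A fit over all classes with at least 10 cells in every library, chosen after the data were seen, lost it too (0.45, adjusted p = 0.271). So did groups of other clusterings matched to cluster 8 by shared cells with no cell filter (788 cells; 0.18, adjusted p = 0.282) and with the stricter one (756 cells; 0.15, adjusted p = 0.383).

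In cluster 8, 2181 of 16827 genes were higher and 2156 lower. They were 1319 and 1101 without library C and 1447 and 1372 without B, and 1574 and 1434 without the block. With library totals and no TMM factors they were 3269 and 1415, which moved the median log2 fold change of all genes from -0.05 to 0.12. GFP did not differ detectably (0.18 ± 0.09, adjusted p = 0.159), nor did Lcn2 (-0.07 ± 0.21, adjusted p = 0.846) or tdtomato (-0.03, adjusted p = 0.858). Of the airway transcripts, Scgb1a1 (4.24; 21595 ± 13950 against 965 ± 143 CPM), Scgb3a2 (7.32), Cyp2f2 (3.38) and Foxj1 (3.97) were higher over the whole cluster. The 15 airway-like cells among its 489, chosen by their Scgb1a1, held 99.2% of its Scgb1a1, 99.7% of its Scgb3a2, 75.5% of its Cyp2f2 and 21.7% of its Foxj1 UMIs. Without these cells and AT2-like cluster 6, Scgb1a1 was lower than in AT2-like cells (-2.46; 174 against 906 CPM), in part by the choice of the cells. Scgb3a2 did not pass (-0.93, adjusted p = 0.581), while Cyp2f2 (1.54) and Foxj1 (3.80) were higher. With 0 UMIs in AT2-like cells, Sntn was at least 83.2-fold, Ackr1 at least 79.9-fold, Iqca at least 63.3-fold and Tekt1 at least 56.6-fold higher in cluster 8. Iqca and Tekt1 were too rare to test once these cells were left out, while Ccl20 (9.88), Gbp2 (6.13) and Cldn4 (6.03) remained higher. The AT2 markers Sftpc (-1.19), Sftpb (-1.23), Lamp3 (-0.64) and Lyz2 (-0.78) were lower, Hopx was higher (1.51), and the AT1 gene Ager did not differ detectably (0.06, adjusted p = 0.880). Fgf18 (chromosome 11, 33117430 to 33147400, minus strand) was rare in cluster 8, with 1 UMI against 201 in AT2-like cells, a 20.1-fold ratio of the scaled sums (95% counting interval 3.57 to 799; fitted log2 fold change -4.37, and -8.71 without library A).

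Of 17 interferon genes 15 were higher in cluster 8 and 0 lower (17 higher when adjusted over the list alone). Isg15 stood at 3.06, with Ifi27l2a (0.82, adjusted p = 0.0590) and Usp18 (0.72, adjusted p = 0.134) short of the threshold. The transitional alveolar list had 12 of 15 higher and 0 lower (14 higher when adjusted over the list alone). Of its genes 10 are among the markers whose score left the cluster unnamed, so this rise restates the naming in part. Tnip3 (4.49), Itgb6 (3.06), Krt19 (3.01) and Krt8 (1.57 ± 0.19; 908 ± 177 against 299 ± 22.8 CPM) passed. Areg (0.62, adjusted p = 0.0599) and Cdkn1a (0.34, adjusted p = 0.108) did not. All 7 MHC class II genes were higher, among them Ciita (1.63), H2-Eb1 (1.39; 1447 ± 116 against 554 ± 69.1 CPM) and Cd74 (0.86). Of 16 surfactant lipid genes 13 were lower and 0 higher, with Insig1 (-1.62), Fasn (-1.48) and Abca3 (-1.45) beside Scd1. Chka did not pass (-0.27, adjusted p = 0.144). The NF-kB list was mixed, with 7 of 14 higher (8 adjusted over the list alone; Tnfaip3 1.64) and 3 lower (Il33 -1.91, Lrg1 -1.52, Il6 -1.33). Cxcl5 was short of the threshold (1.41, adjusted p = 0.0986).

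In the smaller sets of changes, Cdkn2b (1.68), Phlda3 (1.39) and Trp53 (1.14) led the 5 of 12 senescence and p53 genes that were higher (0 lower; Gdf15 0.73, adjusted p = 0.0934). Of 8 stem and Wnt genes 4 were lower and 0 higher (5 lower when adjusted over the list alone), among them Fgfr2 (-0.64) and Id2 (-0.95). Axin2 (-0.56, adjusted p = 0.134) and Nkx2-1 (-0.50, adjusted p = 0.0583) were short of the threshold. Mki67 (2.35) and Mcm5 (1.95) were the 2 of 12 proliferation genes that were higher. Iron genes went both ways (4 of 26 higher, 6 lower; Slc25a37 2.06, Cp 1.84, Tfrc -1.14, Trf -0.97), and library totals without TMM factors turned the balance to 5 higher and 4 lower. The ferroptosis and glutathione list had 4 of 15 higher and 2 lower (5 higher when adjusted over the list alone; Srxn1 1.24, Lpcat3 -0.82, Acsl4 -0.67, Gpx4 0.22 with adjusted p = 0.107). The integrated stress response had 4 of 20 higher (Chac1 1.73) and 1 lower (Vldlr -1.53), but 1 and 1 without library C. The Chac1 call was lost without library A (1.64, adjusted p = 0.249) or C (1.58, adjusted p = 0.131). The dissociation list had 1 of 12 higher and 5 lower, with 1 lower when library B or C was left out. By camera with a preset correlation 8 lists passed. These were interferon (adjusted p = 3.26e-15), transitional alveolar (adjusted p = 1.68e-09), MHC class II and surfactant lipid (both adjusted p = 1.67e-06), senescence (adjusted p = 0.00762), NF-kB (adjusted p = 0.0153), stem and Wnt (adjusted p = 0.0265) and proliferation (adjusted p = 0.0491). None passed with an estimated correlation (adjusted p = 0.111 for interferon, 0.175 for the transitional, MHC class II, NF-kB, stem and proliferation lists, 0.250 for senescence and 0.270 for surfactant lipid).

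**Figure D3:**
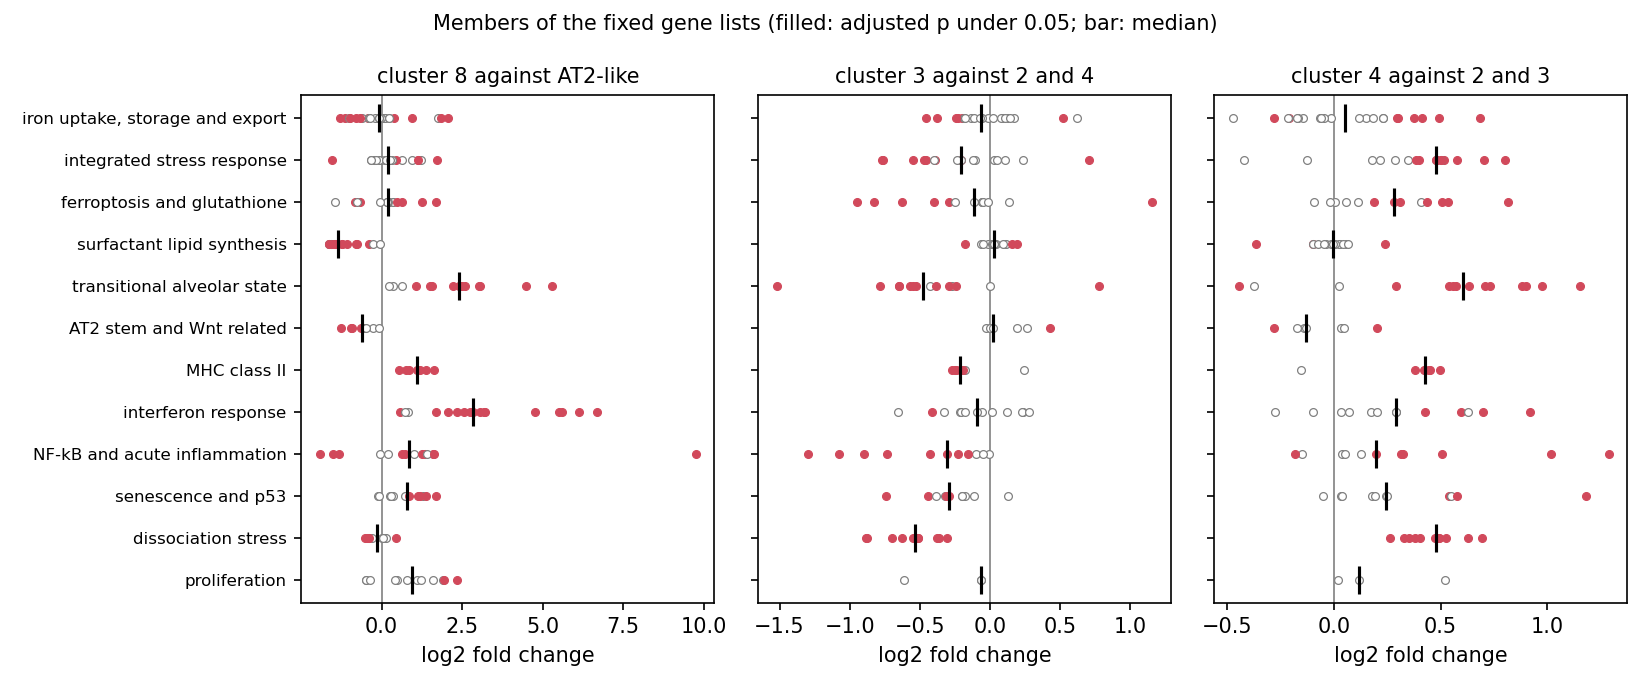
Log2 fold changes (x axes) of the genes of each fixed gene list (y axes) for cluster 8 against AT2-like cells, cluster 3 against clusters 2 and 4, and cluster 4 against clusters 2 and 3; points are genes (filled: adjusted p under 0.05) and bars medians. The interferon list has the highest median in cluster 8 (2.83), while the highest single gene there, Ccl20, belongs to the NF-kB list. All 12 dissociation genes are lower in cluster 3 and higher in cluster 4.

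Of the AT2-like clusters 2, 3 and 4 (1837, 1416 and 1399 cells), cluster 3 was low and cluster 4 high in Areg, Cxcl2 and the 12 dissociation genes. Each cluster was set against the mean of the other 2, so the 3 contrasts sum to 0 and opposite signs in clusters 3 and 4 are built in in part. The dissociation list passed camera with a preset but not with an estimated correlation (adjusted p = 0.142 and 0.136). Areg (chromosome 5, 91139599 to 91148432, plus strand) was 70.6 ± 10.0 CPM in cluster 3 against 206 ± 33.2 in the other 2 clusters (-1.52 ± 0.07, adjusted p = 1.80e-17) and 244 ± 45.7 in cluster 4 against 120 ± 15.3 (1.15 ± 0.06, adjusted p = 3.12e-14). Cxcl2 was -1.30 ± 0.14 in cluster 3 and 1.29 ± 0.13 in cluster 4. Nupr1 was lower in cluster 3 (-0.16 ± 0.05, adjusted p = 0.0239; 302 ± 25.2 against 340 ± 44.7 CPM) and higher in cluster 4 (0.25 ± 0.05, adjusted p = 6.08e-04; 368 ± 63.6 against 307 ± 26.1 CPM). Both Nupr1 calls were lost with library totals in place of TMM factors (-0.08, adjusted p = 0.30, and 0.14, adjusted p = 0.0528) and without the block (-0.17, adjusted p = 0.488, and 0.26, adjusted p = 0.186). They were also lost without library B (-0.12, adjusted p = 0.241, and 0.17, adjusted p = 0.0694), and that of cluster 3 without library C (-0.21, adjusted p = 0.0665) and with DESeq2 (-0.17, adjusted p = 0.0556) and for the matched group of a clustering on more variable genes (-0.11, adjusted p = 0.266). Cluster 6, nearly all from library A (910 of 941 cells), was left out of this comparison.

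Cluster 3 had 1809 of 12285 genes higher and 1328 lower (2310 and 581 with library totals without TMM factors). They were 1137 and 499 without library C, 1283 and 669 without B, 858 and 117 without the block, and 1154 and 658 with DESeq2. Acer1 (3.62 ± 0.33), Trim71 (3.31), Nrxn2 (3.19 ± 0.29; 11.9 ± 1.36 against 1.49 ± 1.16 CPM), Reg4 (3.19) and Slc12a8 (2.94) were among the genes with the largest rises. GFP was lower (-0.51, adjusted p = 2.09e-10; 1364 ± 117 against 1975 ± 237 CPM), and Lcn2 did not pass (-0.14, adjusted p = 0.0760). Between clusters 3 and 4, gene length, depth and the nuclear RNA Malat1 moved with the lists. The log2 fold change of cluster 3 against 4 rose with gene length (Spearman rho 0.433). Malat1 was at 23714, 19712 and 19017 unscaled CPM in cluster 3 of libraries A, B and C and 21035, 13323 and 12432 in cluster 4. Median UMIs of cluster 4 were 0.751, 0.862 and 0.774 of those of cluster 3. Cluster 2 lay near cluster 3 in Malat1 (24608, 19068 and 18567) and in median UMIs (6262, 15246 and 7464.5 against 6619.5, 15681 and 7340). Yet the dissociation list had a median log2 fold change of -0.53 in cluster 3 and 0.10 in cluster 2. Malat1 and depth thus set cluster 4 apart and do not track the lower lists of cluster 3 beside cluster 2. All 12 dissociation genes were lower in cluster 3, with Hspa1a at -0.88 and Fos at -0.63. The transitional alveolar list had 10 of 14 lower (11 adjusted over the list alone; Sfn -0.79, Krt8 -0.54) and 1 higher (Itgb6 0.78). Of 11 NF-kB genes 8 were lower and 0 higher (Cxcl1 -1.08, Il6 -0.90). The integrated stress response had 7 of 17 lower (Ddit3 -0.77) and 1 higher (Mthfd2 0.71). The ferroptosis and glutathione list had 5 of 13 lower (6 adjusted over the list alone; Ptgs2 -0.95, Gclc -0.63) and 1 higher. MHC class II had 5 of 7 lower (H2-Eb1 -0.27, Cd74 -0.25; 6 lower and 1 higher when adjusted over the list alone, 2 lower without library C). Senescence had 4 of 11 lower (Gdf15 -0.74).

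Changes in the other lists were few in cluster 3. Iron genes had 1 of 22 higher and 5 lower (Ftl1 -0.46), turning to 5 higher and 3 lower with library totals. Surfactant lipid had 2 of 15 higher and 1 lower, stem and Wnt 1 of 7 higher (Fgfr2 0.43), interferon 1 of 13 lower (Bst2 -0.41), and none of the 3 proliferation genes passed. By camera with a preset correlation the dissociation (adjusted p = 5.39e-09), transitional alveolar (adjusted p = 3.71e-06), NF-kB (adjusted p = 1.08e-04), integrated stress response (adjusted p = 0.00387), ferroptosis, MHC class II and senescence lists (each adjusted p = 0.0212) passed. None did with an estimated correlation (lowest adjusted p = 0.142, for dissociation).

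Cluster 4, with the gene length, Malat1 and depth differences given above, had 1813 of 12285 genes higher and 1835 lower. They were 1110 and 1224 without library B, 1146 and 1141 without C, 348 and 566 without the block, and 1134 and 1192 with DESeq2. With library totals and no TMM factors they were 1007 and 2667, which moved the median log2 fold change of all genes from 0.01 to -0.10. GFP (0.65 ± 0.04, adjusted p = 1.64e-12; 2336 ± 318 against 1489 ± 128 CPM) and Lcn2 (0.30, adjusted p = 1.15e-04, and 0.19 without library B) were higher. Fbxo2 (1.36), Gdf15 (1.18; chromosome 8, 70629393 to 70632456, minus strand) and Gpx2 (1.19, and 0.73 without library B) were among the genes with the largest rises, and Cacna1b (-1.91) among the largest falls. All 12 dissociation genes were higher (Hspa1a 0.70, Dusp1 0.63, Fos 0.49), as were 11 of 14 transitional alveolar genes (Lgals3 0.98, Krt19 0.90, Krt8 0.71), with Itgb6 lower (-0.45). The integrated stress response had 9 of 17 higher and 0 lower (Asns 0.80, Ddit3 0.70). Ferroptosis and glutathione had 7 of 13 higher and 0 lower (Srxn1 0.81, Gpx4 0.51), and MHC class II 6 of 7 higher (H2-Eb1 0.49, Cd74 0.45). NF-kB had 6 of 11 higher (7 adjusted over the list alone, 3 without library C) and 1 lower. Interferon had 4 of 13 higher (Rtp4 0.92, Bst2 0.70), 2 without library B or C, and senescence 3 of 11 higher (Cdkn1a 0.54).

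Iron genes in cluster 4 included the ferritin genes Ftl1 (0.68) and Fth1 (0.41) and Hmox1 (0.49) among 6 of 22 higher, with Fbxl5 (-0.28) among 2 lower. With library totals the list stood at 6 and 6. Surfactant lipid had 1 of 15 higher and 2 lower (1 and 1 when adjusted over the list alone; Acaca -0.37). Stem and Wnt had 1 of 7 higher and 1 lower (Fgfr2 -0.28), and none of the 3 proliferation genes passed. By camera with a preset correlation the dissociation (adjusted p = 3.49e-06), transitional alveolar (adjusted p = 9.04e-06), integrated stress response (adjusted p = 2.08e-04), MHC class II (adjusted p = 0.00101), and ferroptosis lists (adjusted p = 0.0184) passed. So did NF-kB (adjusted p = 0.0203), senescence (adjusted p = 0.0271) and interferon (adjusted p = 0.0385). None did with an estimated correlation (lowest adjusted p = 0.136, for dissociation and the integrated stress response).

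In cluster 2, Usp54 (0.63 ± 0.07, adjusted p = 1.0e-06), Il6 (0.58), Gclc (0.44), Birc3 (0.41) and Areg (0.37) were higher than in clusters 3 and 4 together, and Reg4 (-3.18), Nrxn2 (-2.62) and Mthfd2 (-0.99) lower. Nupr1 (-0.09, adjusted p = 0.320; 313 ± 27.2 against 335 ± 42.9 CPM) and Lcn2 (-0.16, adjusted p = 0.0583) did not pass, and GFP was slightly lower (-0.14, adjusted p = 0.0257). In all 821 of 12285 genes were higher and 758 lower. Without the block they were 2 and 34, and none of these named genes passed. They were 141 and 182 without library C, 561 and 356 without B, and 521 and 198 with DESeq2. MHC class II had 5 of 7 lower (6 adjusted over the list alone; H2-Eb1 -0.22, Cd74 -0.20; preset adjusted p = 0.00791, and adjusted p = 0.707 with an estimated correlation). It had 3 lower without library B and 2 without C, and was the 1 list that passed camera with a preset correlation. The transitional alveolar list had 6 of 14 lower and 1 higher, NF-kB 3 of 11 higher, and dissociation 3 of 12 higher (4 adjusted over the list alone). Interferon had 3 of 13 lower (1 higher and 3 lower when adjusted over the list alone). Ferroptosis and glutathione had 3 of 13 higher and 1 lower (3 and 3 when adjusted over the list alone), surfactant lipid 2 of 15 higher and 1 lower, and iron 1 of 22 higher and 2 lower (3 lower when adjusted over the list alone). The integrated stress response had 2 of 17, stem and Wnt 2 of 7 and senescence 2 of 11 lower (3 for senescence when adjusted over the list alone), and none of the 3 proliferation genes passed.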

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

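The tests chosen only after the result was seen were list genes kept in the clustering, the fits without cluster 6 and airway-like cells, the fit of 2 classes alone, and the fits of groups matched by shared cells. Over 349 results and their alternatives, 4646 values were compared. Of these, 4115 were labelled the same, 439 kept the direction and lost the threshold, 8 gained it, 72 moved and 12 turned direction. A gene was the same with its direction and side of the threshold kept, and a level or share within its spread. Counts of genes and lists were the same within a fixed fold of the reported count, so they may have changed. The causes were not tested unless stated.

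The macrophage-like share went from 51.5% to 36.6% with at least 1000 genes and 2000 UMIs and at most 10% mitochondrial UMIs, 41.8% at resolution 2, 40.1% with called doublets kept and 41.8% with list genes kept in the clustering. Unnamed clusters there held 10.6 and 5.17% with the stricter filter, 5.92 and 3.77% at resolution 2, 10.5% with doublets kept and 9.78% with list genes kept. At resolution 0.5 the AT2-like share was 29.9% (23.2% in library A, from 40.3%), with an unnamed cluster of 1521 cells. Most of its cells came from library A (1169, against 147 from B and 205 from C). Nupr1 in AT2-like cells was 317 CPM without TMM factors, 418 without the 10 genes with the most UMIs and 405 with doublets kept, and 28.2 in macrophage-like cells under the stricter filter. Shares of cells with a Nupr1 UMI followed depth by construction: 79.3% of AT2-like and 23.7% of macrophage-like cells unthinned, 24.3 and 3.43% at 1000 UMIs.

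Without the replicate block, the paired part of the fit, cluster 8 had 1434 genes lower, cluster 2 had 2 higher and 34 lower, cluster 3 had 858 and 117, and cluster 4 had 348 and 566. Of 306 calls of named genes with a value there, 120 were lost, among them Nupr1 in cluster 8 (0.45, adjusted p = 0.0920), cluster 3 (-0.17, adjusted p = 0.488) and cluster 4 (0.26, adjusted p = 0.186). AT2-like against macrophage-like cells had 5729 higher and 6474 lower. With library totals and no TMM factors, cluster 8 had 1415 and cluster 3 had 581 genes lower, cluster 4 had 1007 higher, and Nupr1 lost its call in cluster 3 (-0.082, adjusted p = 0.30) and cluster 4 (0.14, adjusted p = 0.0528). With no filter on low counts, cluster 8 had 3731 genes lower and Nupr1 at 0.25 (adjusted p = 0.0777). DESeq2's Wald test gave 521 and 198 in cluster 2, 1154 and 658 in cluster 3 (Nupr1 -0.17, adjusted p = 0.0556) and 1134 and 1192 in cluster 4. With an estimated correlation, 0 lists passed in each of the 5 comparisons.

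Of the 12 turned values 8 were of reporters and Lcn2 in cluster 8, none past the threshold before: GFP at -3.25e-05 with no filter, tdtomato at 0.15 without TMM factors, 0.016 without cluster 6 and airway-like cells and 0.012 for the matched group with list genes kept, and Lcn2 at 0.10 without TMM factors, 0.17 without library C (-0.36 without library A), 0.168 for the matched group at resolution 2 and 0.227 with list genes kept. The other 4 were of matched AT2-like groups, none past the threshold there: Ifi27l2a in cluster 2 (0.148), Hmgcs1 in cluster 3 (-0.102) and Scd1 in cluster 4 (0.0089) at resolution 2, and Ifitm3 in cluster 4 (-0.018) with more variable genes.

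Leaving out libraries A, B and C in turn gave 1319 to 1975 genes higher and 1101 to 2273 lower in cluster 8, 141 to 660 and 182 to 591 in cluster 2, 1137 to 1951 and 499 to 1330 in cluster 3, and 1110 to 1679 and 1141 to 1668 in cluster 4. The lowest counts were without library C, or B for genes higher in cluster 4, and the highest without A. With 2 libraries in place of 3, fewer calls follow in part from the smaller number of sums. Nupr1 ran from 0.33 (no A) to 0.52 (no C, adjusted p = 0.0520) in cluster 8, from -0.21 (no C, adjusted p = 0.0665) to -0.12 (no B, adjusted p = 0.241) in cluster 3 and from 0.17 (no B, adjusted p = 0.0694) to 0.33 (no C) in cluster 4.

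Clustering alternatives for AT2-like against macrophage-like cells were fitted with the 2 classes alone, which gave 6675 genes higher and 6300 lower in the reported clustering. Cluster 8 was matched in 5 other clusterings, and clusters 2 to 4 in 3, to groups where shared cells were at least 0.5 of the cells in either. There Ccl20 in cluster 8 ran from 8.24 to 9.44 and Scd1 from -1.41 to -1.28, with 14 to 17 interferon, 7 MHC class II and 0 surfactant lipid genes higher and 13 to 14 surfactant lipid genes lower. Nupr1 in cluster 8 lost its call with no cell filter (0.184, adjusted p = 0.282) and the stricter one (0.149, adjusted p = 0.383), and kept it at resolution 2 (0.561), with more variable genes (0.338) and with list genes kept (0.517). In cluster 3, Nupr1 (-0.115, adjusted p = 0.266) and the genes lower (712) moved with more variable genes. Cluster 8 and the set of clusters 2 to 4 could not be matched so at resolution 0.5 or with doublets kept, nor that set with no cell filter or with list genes kept. The alternatives planned for age and hairpin were not run, since no cell carried either.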

Other observations

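The tests of GFP in macrophage-like cells, the values of the smaller classes and the choice and wording of the splits counted were chosen only after the result was seen. The test of cluster 6's leading genes within macrophage-like cells was added after the first results on that cluster and before its own.

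Smaller classes with at least 10 cells in every library were fitted with edgeR for listed genes in a fit of their own. Against AT2-like cells Nupr1 was lower in AT1-like (-2.71, adjusted p = 1.74e-05), endothelial-like (-4.05, adjusted p = 1.57e-09), monocyte or dendritic (-2.98, adjusted p = 4.74e-08) and B-cell-like cells (-5.71, adjusted p = 1.81e-08), each in 3 of 3 libraries. Fibroblast-like cells (-0.09, adjusted p = 0.829) and cluster 15 (-0.98, adjusted p = 0.158) did not pass for Nupr1, and neither did cluster 8 in this fit (0.45, adjusted p = 0.271). GFP was lower in fibroblast-like (-0.75, adjusted p = 0.00402) and endothelial-like cells (-3.36), and did not pass in AT1-like cells (-0.34, adjusted p = 0.262) or cluster 15 (0.12, adjusted p = 0.929). Lcn2 was lower in AT1-like (-2.87) and fibroblast-like cells (-5.21). Of 17 interferon genes 16 were higher than in AT2-like cells in endothelial-like, fibroblast-like and monocyte or dendritic cells alike, and 7 in AT1-like cells. AT1-like cells had 12 of 16 surfactant lipid genes lower, 8 of 15 transitional alveolar genes higher and 1 lower, and 6 of 12 senescence and p53 genes higher. MHC class II had 7 of 7 genes lower in fibroblast-like and 7 of 7 higher in monocyte or dendritic cells.

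Cluster 6 of the AT2-like cells came almost only from library A (910 of 941 cells), with Scin, Necab2, Dnah12 and Fam171b as leading genes. Shallow or damaged cells are argued against, since its median UMIs were 1.03 times those of clusters 2 to 4 of library A and its mitochondrial share 0.924 times theirs. A cause that covers all of library A stays open. The 10 leading genes had a median log2 ratio of 1.71 in macrophage-like cells of A over B and C (from -0.15 to 3.06). Over 1 had been foreseen, and the median in clusters 2 to 4 was 1.06. This test cannot decide, since free RNA from cluster 6 in other droplets of A would raise these genes too. Within A their log2 ratio of cluster 6 over clusters 2 to 4 was 1.30 to 3.68, in part by their choice. Another sex make-up of the animals behind the cluster stays open. Of its cells 21.1% had a UMI of Ddx3y, Uty, Kdm5d or Eif2s3y, against 61.2% in clusters 2 to 4 of A (-40.1 percentage points). A library-wide cause alone does not predict this gap within a library. Clusters 2 to 4 of libraries B and C had 51.9 and 19.0%, so a low share was not particular to cluster 6. Whether macrophage-like cells of A with a leading gene come from the same animals cannot be told apart (57.9 against 64.0% with a Y-linked UMI, -6.05 points, between the 3 and 10 set beforehand). Cells with a leading gene were deeper (median 5557 against 4936 UMIs) and were not thinned, so this gap may be understated. Age and hairpin are untested for want of labels.

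Each set against the mean of the other 2, clusters 3 and 4 had most lists changed at once by camera with a preset correlation. None passed with an estimated correlation (lowest adjusted p = 0.142 in cluster 3 and 0.136 in cluster 4). The lists were not tested for cluster 3 against 4 directly. The share of nuclear or unspliced RNA may contribute: across 12222 genes, which are not independent replicates, the log2 fold change of cluster 3 against 4 rose with gene length (Spearman rho 0.433; 0.289, 0.381 and 0.395 in libraries A, B and C), with a median of -0.25 in the shortest 25% of genes and 0.26 in the longest. The nuclear RNA Malat1 was lower in cluster 4 in 3 of 3 libraries (21035 against 23714, 13323 against 19712 and 12432 against 19017 unscaled CPM). Depth cannot be told apart as a cause of the differences between clusters 3 and 4. There, median UMIs of cluster 4 were 0.751, 0.862 and 0.774 of those of cluster 3 in libraries A, B and C. Those of A and C lie between the bounds set beforehand for no difference and for a difference, and that of B within the former, which was to hold in every library. Median UMIs of cluster 2 (6262, 15246 and 7464.5) lay near those of cluster 3 (6619.5, 15681 and 7340), and so did its Malat1. Depth and Malat1 therefore do not track the lower lists of cluster 3 beside cluster 2. No biological explanation was tested.

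GFP in macrophage-like cells is not readily laid to free RNA in the droplets, as it was at least 3.80 times that of B-cell-like cells in each library (4.65, 3.80 and 5.48). With called doublets kept the means were 634 against 265 CPM, and with the stricter filter 594 against 205. Content of AT2 cells is argued against too: the median of 9 AT2 markers (Lyz2 left out as a macrophage gene, a choice made in the test) reached 0.574, 1.44 and 0.804% of the AT2 level in macrophage-like cells where GFP reached 32.4, 35.2 and 39.8%, at most 0.0409 of the GFP ratio. Macrophages that took up the Cre vector stay open as a candidate explanation, since Cre was higher in macrophage-like than in AT2-like cells in 3 of 3 libraries (AT2-like against macrophage-like -2.01). Sorting on GFP acts on both classes, so the levels say nothing of unsorted cells.

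Other splits of the same sums were fitted with edgeR and the block, and those with 1 sum of each library in the group of 3 were counted. For AT2-like against macrophage-like cells and for cluster 8 against AT2-like cells, 1 of 4 such splits gave as many genes, the real one (12975 and 4693 genes, highest other 0), and 4 splits are too few for a share under 0.05. For cluster 4, 1 of 27 splits gave as many genes as the real one (2318; highest other 1052, the split of cluster 3), and for cluster 3, 2 of 27 (1052; highest other 2318, the split of cluster 4). For cluster 2 the real split, with clusters 3 and 4 as 1 group, gave 0 genes (1079 at an unadjusted p under 0.05), so 27 of 27 gave as many by construction (highest other 2318), and its counts rest on the fit that keeps clusters 3 and 4 apart. The classes and clusters were formed from the same cells' expression, so splits that mix them (0 genes in each fitted) were bound to give fewer, and these counts do not decide on chance. The other 54 splits fitted, without 1 sum of each library, gave 0 genes too, and the 3 that follow the libraries could not be fitted with the block.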
